A study of Homo sapiens with 18 samples.

How the data were processed

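The labels state that the cells grew in RPMI with 10% serum and were collected above 70% confluency, and that RNA was extracted with TRIzol, cleaned on columns with DNase, labelled as biotinylated cRNA with a 3′ IVT kit and hybridized to PrimeView arrays. The deposited table holds log2 values, and the submitters' processing notes name MAS5, whose version they do not give. The values were used as deposited, without further scaling in the analysis reported first. It has 49395 probe sets, of which 102 are controls. The annotation gives a single gene symbol for 44988 probe sets, several for 1832 and none for 2473. Of the symbols, 44961 were matched through gene identifiers and 0 changed. Detection calls were not used here. Mature microRNA levels were not analysed here, so the degree of overexpression is not given.

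Each gene was read by the probe set with the highest mean among those with a single gene symbol. The gene was kept if that probe set lay above the median of its own array in at least 2 arrays, which left 15087 of 18132 genes. Linear models were fitted to all 18 arrays at once with limma, with 1 mean for each of the 7 groups, moderated variances with a trend on the mean, and 11 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 are called changed. The comparisons were each microRNA against Control in each line, Control against Wildtype, miR-195 against miR-30d in each line, the difference between lines in each effect, and the Controls of both lines.

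The design, the comparisons, the gene lists and the rule for naming genes were fixed before the data were examined. For the 4 microRNA comparisons and Control against Wildtype the rule takes the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05 and groups that do not overlap. Where fewer than 5 pass in a direction, all that pass are taken with those of smallest p up to 5. It adds up to 4 members of each list with the smallest p, and RPS6KB1, FOSL1, VEGFA, BCL2, CCND1 and CCNE1 for miR-195 and PPP1R12A, SOCS1, JUN and VEGFA for miR-30d as targets reported elsewhere. The report gives part of these genes in full.

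Gene lists were tested with camera at a preset correlation of 0.01 between genes, and beside it with camera at an estimated correlation and with fry. The 25 lists, written from general knowledge, were reported targets of miR-195 and of miR-30, microRNA machinery, G1/S and DNA replication, G2/M and mitosis, androgen-responsive genes, epithelial, mesenchymal and neuroendocrine markers, angiogenesis, immediate early and AP-1 genes, hypoxia and glycolysis, cholesterol synthesis, the unfolded protein and ATF4 response, interferon response, p53 targets, apoptosis regulators, NF-kB and inflammation, ribosomal proteins, the respiratory chain, histones, identity markers of LNCaP and of DU145, markers of immune and blood cells, and markers of fibroblasts and endothelium.

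The code was tested on simulated data with 50 genes at each size, raised or lowered at random. Of genes changed by a factor of 1.5, it recovered 20% for LNCaP miR-195, 12% for LNCaP miR-30d, 6% for DU145 miR-195, 8% for DU145 miR-30d and 8% for Control against Wildtype. For a factor of 2 the shares were 74%, 72%, 54%, 40% and 60%, and for a factor of 4 they were 100%, 98%, 98%, 98% and 98%. The false calls numbered 9, 13, 6, 11 and 6. The software was R 4.3.3, limma 3.58.1, version 1.17.8 of data.table, Python 3.11.15 and matplotlib 3.10.9. Alternatives tried were offsets on the linear scale, quantile scaling within and across lines, subtraction of array medians, other filters, other ways of choosing probe sets, a replicate block, other variance settings, arrays of 1 line alone, Wildtype in place of Control, and each array left out.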

Results

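Transcript levels were measured in 18 samples labelled as human prostate cancer cells, each on 1 Affymetrix PrimeView array, an oligonucleotide array whose probe sets lie mostly near the 3′ end of transcripts. LNCaP is an androgen-responsive prostate cancer line taken from a lymph node metastasis, and DU145 is an androgen-independent line taken from a brain metastasis. The lines had been made to overexpress miR-195 or miR-30d, microRNAs that repress the messenger RNAs they pair with, by infection with a packaged virus and stable selection. The Control lines carried a scramble vector. For LNCaP there were 3 arrays each of miR-195, miR-30d, Control and untransduced Wildtype cells, and for DU145 there were 2 arrays each of miR-195, miR-30d and Control cells. The series set out to study the function of these microRNAs in both lines. Nothing in the labels says that arrays of a group came from separate cultures, and if they did not, the p-values measure only the spread between these samples. The number of arrays per group limits the precision of every value. Differences are log2 signal differences, and the value after ± is their standard error, except where an SD is named. The standard errors and p-values use a spread pooled over all 7 groups. Most of its degrees of freedom come from the arrays labelled LNCaP. For genes that vary more in DU145 cells, the errors there are too small.

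The arrays labelled LNCaP lacked the signal of many transcripts that were abundant in the arrays labelled DU145, including genes used by nearly all human cells. The log2 signal of HPRT1, a purine salvage enzyme, was 3.64 ± 0.24 (SD, n = 12) in the arrays labelled LNCaP and 9.50 ± 0.27 (SD, n = 6) in the arrays labelled DU145. For B2M, the light chain of class I histocompatibility molecules, the means were 4.08 and 11.72, and for PPIA, an abundant prolyl isomerase, they were 4.63 and 12.75. The median of 39 ribosomal protein genes was 7.88 in the arrays labelled LNCaP, where 20 of the 39 lay under 8, and 12.55 in the arrays labelled DU145, where 0 of the 39 did. Other abundant transcripts were high under both labels, among them VIM, the mesenchymal intermediate filament vimentin, at 12.16 and 12.68, and EEF1A1, a translation elongation factor, at 12.45 and 12.78. Most LNCaP identity markers were higher under the LNCaP label, but their signal was low. All 12 lay under 8 in those arrays, with a list median of 5.215, where the 75th percentile of all probe sets averaged 5.20. KLK3, the prostate-specific antigen, had a mean signal of 5.51 there and 3.80 under the DU145 label, KLK2, a related protease, 6.60 and 4.37, TMPRSS2, a membrane protease, 6.62 and 5.16, and HOXB13, a prostate homeobox factor, 6.51 and 4.08. SLC45A3 stood at 5.85 and 3.71 and SPDEF at 7.43 and 4.83, whereas FOXA1, a transcription factor of luminal prostate cells, stood at 3.71 and 8.32 and the simple-epithelial keratins KRT18 and KRT8 at 4.89 and 5.50 against 12.16 and 10.14. In all, 9 of 12 markers were higher under the LNCaP label, as were 12 of 12 markers of immune and blood cells and 11 of 11 of fibroblasts and endothelium.

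The control probe sets along ACTB also differed. The 3′ minus 5′ signal was -2.59 ± 0.24 (SD, n = 12) in the arrays labelled LNCaP and 3.13 ± 0.32 (SD, n = 6) in the arrays labelled DU145. The control probe set for Alu repeats averaged 10.46 under the LNCaP label and 13.29 under the DU145 label. Spike-ins for hybridization averaged 11.02 and 9.19, and the probe sets for 18S ribosomal RNA 13.70 and 11.50. The cause of these differences was not tested. Across genes, arrays with different line labels correlated at r between 0.383 and 0.595, and arrays of the same group at r of at least 0.948. Genes are not independent replicates. The 99th percentile of the signal lay between 8.99 and 9.42 in the arrays labelled LNCaP and between 10.81 and 11.03 in those labelled DU145. The 75th percentile ran from 5.03 to 5.24 and from 5.40 to 5.62, a spread within a line wider than the gap between lines. The mean linear signal ran from 51.2 to 58.4 and from 106.4 to 115.3, a gap beyond the spread within a line. These measures do not tell whether the lines were scaled separately before deposit, and levels set side by side across lines carry that limit. The array of LNCaP miR-195 replicate 1 had the lowest 99th percentile of all and a mean linear signal of 51.2, where the other arrays labelled LNCaP had up to 58.4. Results for these 12 arrays are therefore given as results of the arrays labelled LNCaP.

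**Figure D1:**
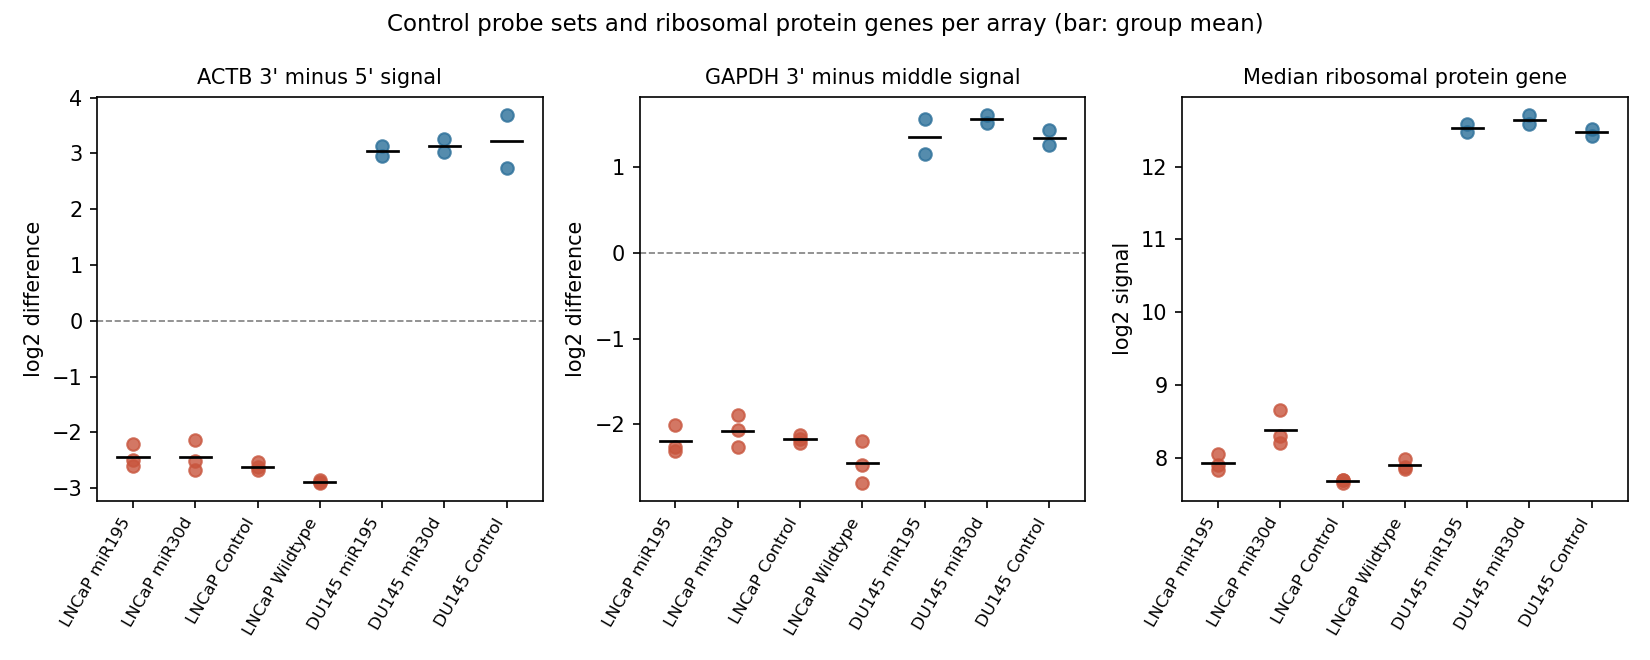
Each point is 1 array, grouped by label on the horizontal axis, with LNCaP in red and DU145 in blue, and black bars are group means. The vertical axes give the log2 difference between 3′ and 5′ probe sets of ACTB, the log2 difference between 3′ and middle probe sets of GAPDH, and the log2 signal of the median ribosomal protein gene; the arrays labelled LNCaP average -2.59 for the first and -2.22 for the second, against 3.13 and 1.42 in the arrays labelled DU145.

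Of 15087 genes tested, 7513 changed in DU145 miR-195 cells and 1991 in DU145 miR-30d cells against their Control, and 1000 and 27 in the arrays labelled LNCaP with miR-30d and miR-195. The comparisons took up what each microRNA does in each line, whether the scramble vector itself changes the untransduced cells, whether the microRNAs differ from each other, and whether their effects differ between lines.

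**Figure D2:**
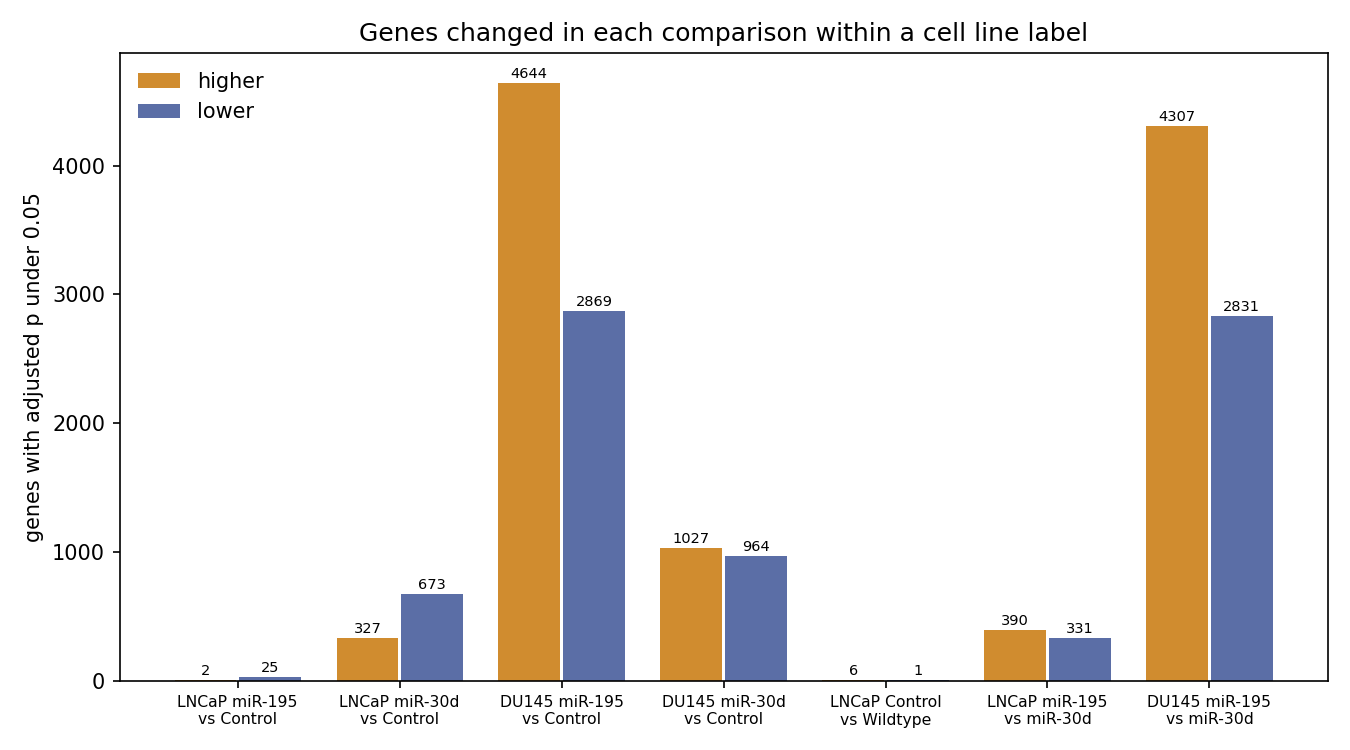
Bars give the number of genes with an adjusted p under 0.05 (vertical axis, from 0) that were higher or lower in the first named group of each comparison (horizontal axis), out of 15087 genes tested. The DU145 miR-195 arrays had 4644 genes higher and 2869 lower than Control, and LNCaP Control against Wildtype had 6 higher and 1 lower.

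In the arrays labelled LNCaP, miR-195 was accompanied by falls in a small set of genes led by TFEC, a transcription factor of the MITF family, which fell by 5.44 ± 0.23 (adjusted p = 1.01e-12). DACH1, a nuclear cofactor of developmental gene control, fell by 3.18 ± 0.29, ZFHX3, a homeobox factor, by 3.05 ± 0.37, and GCC2, a golgin of the trans-Golgi network, by 2.13 ± 0.20. SMARCA1, a chromatin remodelling ATPase, fell by 1.79 ± 0.25, MLLT3, a subunit of the super elongation complex, by 1.58 ± 0.24, and ATP6AP2, an accessory subunit of the vacuolar proton pump, by 1.47 ± 0.21. Of the genes with higher signal, PSMG4, a proteasome assembly chaperone, rose by 0.76 ± 0.14 (adjusted p = 0.0203), and S100A13 rose by 0.78 ± 0.16 (adjusted p = 0.0498). PTGES3, ENO1 and RPL9 had log2 differences of 0.86, 0.60 and 0.51 and missed the threshold, with adjusted p of 0.0641, 0.0655 and 0.0700. None of the 32 measured genes reported elsewhere as miR-195 targets passed, nor did the list (camera, adjusted p = 0.862), and CCND1, CCNE1 and BCL2 had log2 differences of -0.27, -0.03 and -0.49. Their 3 adjusted p were 0.788, 0.984 and 0.711. In the Control arrays CCND1, CCNE1 and BCL2 stood at 3.48, 3.97 and 5.69, where the array median averaged 3.91. CCND1 and CCNE1 thus had little room to fall. The target list had a median of 5.07 in the arrays labelled LNCaP, with 30 of 32 genes under 8, which limits this result.

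In all, 27 genes passed, 2 higher and 25 lower, and 18 of the 25 fell by at least 1. Without adjustment 1197 genes had p under 0.05. After quantile scaling across all arrays 42 genes passed, 8 higher and 34 lower. ZFHX3 and GCC2 were read by probe sets that can match several transcripts, and without such probe sets their differences were 0.13 and 0.03. With the mean of all probe sets of a gene, ATP6AP2 had a difference of -0.51 (adjusted p = 0.113), GCC2 of -0.48 (adjusted p = 0.300) and PSMG4 of 0.23 (adjusted p = 0.825). With an offset of 16, S100A13 had 0.53 (adjusted p = 0.0857). The count depended on single arrays, falling to 9 without miR-195 replicate 1, to 12, 10 and 8 without Control replicates 1, 2 and 3, and rising to 180 without miR-195 replicate 3. PSMG4 and S100A13 were each past the threshold without only some of the arrays, PSMG4 in 2 of the 6 cases and S100A13 in 1 of the 6. Of 25 gene lists fixed beforehand, only the ribosomal protein list passed camera, with a median difference of 0.18 over 39 genes (adjusted p = 1.48e-09), none of the 39 past the test over all genes and 4 higher when adjusted over the list alone. With an estimated correlation between genes its adjusted p = 0.712. The median ribosomal protein gene stood at 7.93 in miR-195, 7.69 in Control and 7.90 in Wildtype arrays, so this call rests on low values in the Control. Without miR-195 replicate 1 or Control replicate 2 the number of lists past the threshold was 2.

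Of the 10 largest falls with miR-195, 5 were in genes that also set the Control apart from the untransduced cells. In LNCaP Control against Wildtype, TFEC was higher by 4.28 ± 0.23, DACH1 by 2.63 ± 0.29, SMARCA1 by 1.96 ± 0.25, GCC2 by 1.89 ± 0.20, TIMP2, an inhibitor of matrix metalloproteinases, by 1.59 ± 0.20 and MLLT3 by 1.35 ± 0.24. PSMG4 was lower by -0.83 ± 0.14. Not all of these held with other probe sets. With the mean of all probe sets TIMP2 had a difference of 0.61 (adjusted p = 1), GCC2 of 0.44 (adjusted p = 0.881), MLLT3 of 0.76 (adjusted p = 0.199) and PSMG4 of -0.23 (adjusted p = 1), and GCC2 had -0.11 without probe sets that can match several transcripts. These were all of the 7 genes past the threshold, with 622 genes at an unadjusted p under 0.05. Among the other large falls, ZFHX3 had a difference of 1.16 ± 0.37 between Control and Wildtype (adjusted p = 0.826), ATP6AP2 of 0.89 ± 0.21 (adjusted p = 0.294) and PRRX1, a mesenchymal homeobox factor, of 0.11 ± 0.25 (adjusted p = 0.999). MLLT3 lost its call without any 1 of the 6 arrays (adjusted p up to 0.349), and PSMG4 was past the threshold in 2 of the 6 cases. Several of these genes were lower with miR-30d too: against Control, TFEC differed by -2.39, DACH1 by -2.61, SMARCA1 by -2.16 and MLLT3 by -1.86, with adjusted p of at most 1.85e-05. When Wildtype took the place of Control, 5 genes passed for miR-195, all lower, and 2 of them were among the 27. TFEC then differed by -1.15 (adjusted p = 0.0894), DACH1 by -0.55 (adjusted p = 0.883), ATP6AP2 by -0.58 (adjusted p = 0.833), ZFHX3 by -1.89 (adjusted p = 0.0748), GCC2 by -0.24 (adjusted p = 0.900), MLLT3 by -0.24 (adjusted p = 0.920) and SMARCA1 by 0.17 (adjusted p = 0.944). The lists of hypoxia and glycolysis, ribosomal protein, respiratory chain and histone genes passed camera as lower in Control than in Wildtype, with medians of -0.10, -0.20, -0.14 and -0.22 and no member past the test over all genes. With an estimated correlation the adjusted p were 0.419, 0.419, 0.852 and 0.524. Adjusted over the list alone, 2 hypoxia and glycolysis genes and 4 ribosomal protein genes were lower. Of these lists, 2 were past the threshold without Control replicate 1 or Control replicate 3, where the respiratory chain had adjusted p of 0.0843 and 0.361 and the histones of 0.0937 and 0.361. Only the ribosomal protein list was without Wildtype replicate 1 or Wildtype replicate 2, where hypoxia and glycolysis had adjusted p of 0.0514 and 0.0766, the respiratory chain of 0.305 and 0.0766 and the histones of 0.190 and 0.0932.

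**Figure D3:**
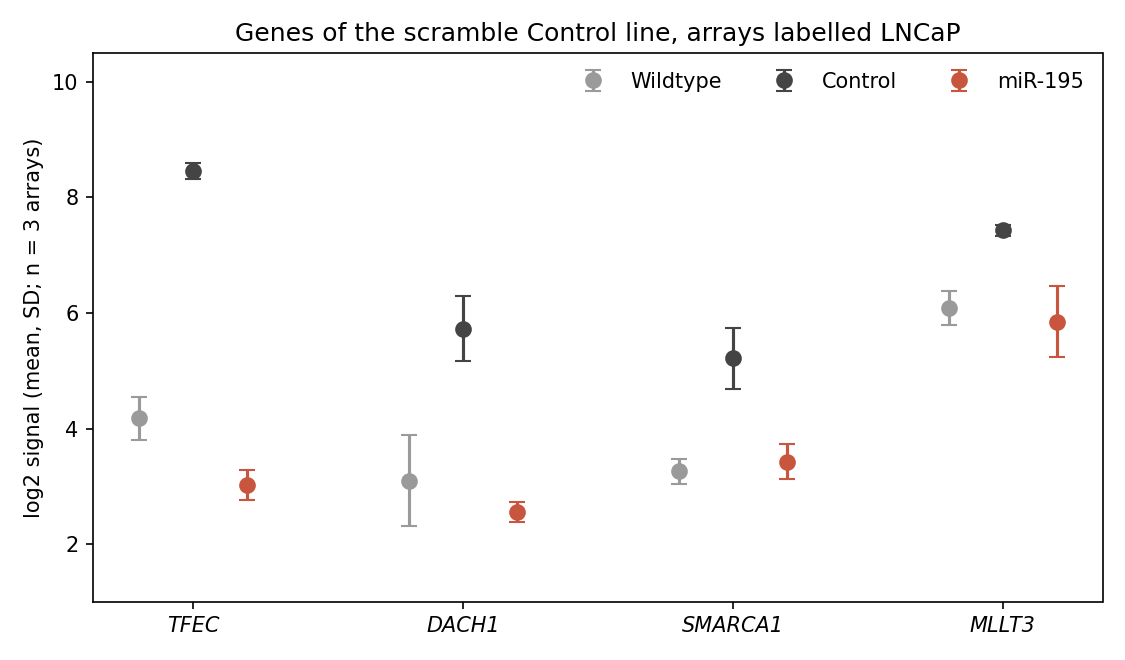
Points give the mean log2 signal (vertical axis) and error bars the SD of 3 arrays each for 4 genes (horizontal axis) in the Wildtype, Control and miR-195 cells labelled LNCaP. TFEC stands at 8.46 in Control, 4.18 in Wildtype and 3.02 in miR-195 arrays, and the other 3 genes are likewise highest in Control.

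With miR-30d in the arrays labelled LNCaP, some of the genes reported elsewhere as targets of the miR-30 family fell. Of 36 measured targets 9 fell and 1 rose, the same counts when adjusted over the list alone, with a list median of -0.13 (camera, adjusted p = 5.06e-05). The list missed the threshold with an estimated correlation (adjusted p = 0.0695). BECN1, a core autophagy protein, fell by 1.43 ± 0.17, EED, a Polycomb subunit, by 1.47 ± 0.19, GALNT7 by 1.90 ± 0.23 and GALNT1 by 2.86 ± 0.38, both enzymes that start mucin-type glycosylation. For GALNT1, 2 of 5 probe sets moved this way. PPP1R12A, the myosin phosphatase targeting subunit named beforehand as a miR-30d target, fell by 3.49 ± 0.48 (adjusted p = 4.35e-05), with all 5 of its probe sets lower. SOCS1 and JUN, also named beforehand, had log2 differences of 0.09 and -0.34 (adjusted p of 0.876 and 0.429). VEGFA, the endothelial growth factor, fell by 1.20 ± 0.15 (adjusted p = 1.65e-05), with 9 of its 10 probe sets lower. It differed by 0.11 when probe sets that can match several transcripts were left out, where another probe set read the gene.

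Larger falls lay outside that list. ATP2B1, a calcium pump of the plasma membrane, fell by 4.49 ± 0.53, STRBP, an RNA-binding protein, by 4.04 ± 0.46, FRMD4A and FRMD4B, scaffolds of cell junctions, by 3.52 ± 0.21 and 3.25 ± 0.34, and STRN3, a subunit of a phosphatase complex, by 3.23 ± 0.34. ZFHX3 fell by 4.60 ± 0.37, and by only 0.17 without probe sets that can match several transcripts (adjusted p = 0.807). ZEB2 and ZEB1, repressors of epithelial genes, fell by 2.85 ± 0.42 and 2.16 ± 0.37, though ZEB1 had -0.70 (adjusted p = 0.0573) with the mean of all probe sets, and HSPA5, a chaperone of the endoplasmic reticulum, by 1.56 ± 0.26. ADSL, an enzyme of purine synthesis, rose by 1.55 ± 0.18, ID3, an inhibitor of helix-loop-helix factors, by 1.41 ± 0.14, and PSMB3, a proteasome subunit, by 1.22 ± 0.14. Of 39 ribosomal protein genes 20 rose and 1 fell (27 and 1 adjusted over the list alone), with a median of 0.67 (camera, adjusted p = 9.04e-19, and 0.0695 with an estimated correlation), among them RPLP1 at 0.90 ± 0.10 and RPS23 at 0.94 ± 0.12. Of 33 respiratory chain genes 10 rose and 1 fell (12 and 2 adjusted over the list alone), led by NDUFV1 at 0.99 ± 0.17 and NDUFS3 at 0.96 ± 0.15 (camera, adjusted p = 8.00e-07, and 0.0695 with an estimated correlation). Of 10 histone genes 2 rose, over all genes and over the list alone, with a median of 0.38 (camera, adjusted p = 0.0196, and 0.215 with an estimated correlation). These were H2AC6 and H2BC5, and with Wildtype in place of Control they had differences of 0.57 (adjusted p = 0.103) and 0.35 (adjusted p = 0.479). H2BC5 also lost the call with an offset of 64 (adjusted p = 0.110) and with the mean of all probe sets (adjusted p = 0.505). The histone list was not past the threshold without miR-30d replicate 1 (adjusted p = 0.0728) or Control replicate 3 (adjusted p = 0.0931).

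In this comparison 1000 genes passed, 327 higher and 673 lower, of which 47 and 410 changed by at least 1. Without Control replicate 3 the count was 653, and with Wildtype in place of Control it was 687. The poly-A spike-in transcripts are control RNAs added before labelling, in an amount per sample that was not checked here. Their mean signal was 9.43 ± 0.02 (SD, n = 3) in the miR-30d arrays and 7.48 ± 0.54 (SD, n = 3) in the Control arrays. This difference of 1.95 accompanied the changes in each of the groups above. The corresponding difference for miR-195 was 0.15.

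In DU145 cells miR-195 was accompanied by broad change, with falls of many mitotic and DNA replication genes and rises of many histone and respiratory chain genes. The median over all tested genes was 0.30 higher than in Control and 0.38 higher after each array median was subtracted, so list medians below are also given relative to the median of all genes. Of 33 genes of G2/M and mitosis 22 fell and 4 rose (22 and 5 adjusted over the list alone), with a median of -1.36 and -1.65 relative to all genes (camera, adjusted p = 5.78e-09, and 0.145 with an estimated correlation). CENPF and CENPE, kinetochore proteins, fell by 4.82 ± 0.31 and 3.97 ± 0.23, TOP2A, the topoisomerase of dividing cells, by 4.86 ± 0.39, and KIF11, a motor of the mitotic spindle, by 4.46 ± 0.25. Of 33 genes of G1/S and DNA replication 14 fell and 1 rose, with the same counts when adjusted over the list alone, at a median of -0.51 relative to all genes (camera, adjusted p = 0.00461, and 0.272 with an estimated correlation). MCM10, a replication initiation factor, fell by 3.29 ± 0.27 and POLA1, the catalytic subunit of DNA polymerase alpha, by 3.17 ± 0.30. SMC2 and SMC3, subunits of condensin and cohesin, fell by 5.35 ± 0.23 and 5.22 ± 0.50, and MYBL1, a transcription factor, by 5.54 ± 0.29, the largest fall among the named genes. Of 10 histone genes 8 rose, over all genes and over the list alone, with a median of 1.52 relative to all genes (camera, adjusted p = 0.00248, and 0.145 with an estimated correlation), among them H2AC6 at 2.88 ± 0.23 and H1-2 at 2.73 ± 0.24.

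Several genes of the machinery that makes and uses microRNAs fell as well. Of 16 such genes 7 fell and 1 rose, the same when adjusted over the list alone, with a median of -1.06 relative to all genes (camera, adjusted p = 0.0195, and 0.145 with an estimated correlation). DICER1, the enzyme that cuts microRNA precursors, fell by 2.58 ± 0.28, DROSHA, the nuclear enzyme before it, by 1.88 ± 0.28, TNRC6A by 2.04 ± 0.32 and AGO4 by 1.75 ± 0.30, both proteins of the silencing complex. This list was not past the threshold with an offset of 16 (adjusted p = 0.0542) or without Control replicate 2 (adjusted p = 0.102), where 5 of the 25 lists were, against 8 with all arrays. Of 36 reported miR-30 targets 14 fell and 8 rose (14 and 9 adjusted over the list alone; median -0.42 relative to all genes; camera, adjusted p = 0.0195, and 0.272 with an estimated correlation), with CHD1 lower by -3.68 ± 0.31 and TWF1 by -3.41 ± 0.25. Of 32 reported miR-195 targets 9 fell and 6 rose, over all genes and over the list alone, and the list missed the threshold (camera, adjusted p = 0.184). Its median was 0.08 while its mean was -0.37. KIF23, a motor of cytokinesis, fell by 4.01 ± 0.27, CHEK1, a checkpoint kinase, by 2.06 ± 0.28 and CCND1, cyclin D1, by 1.26 ± 0.26, whereas ARL2, a small GTPase, rose by 1.97 ± 0.28. CCNE1, BCL2, RPS6KB1, FOSL1 and VEGFA, also named beforehand, had log2 differences between -0.14 and 0.55 and adjusted p of at least 0.204. PPP1R12A, a reported miR-30d target, fell by 4.21 ± 0.59 (adjusted p = 4.07e-06).

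Among the genes that rose, SCARNA14, a small Cajal body RNA, was higher by 5.97 ± 0.73, AKR1C3 and AKR1C2, aldo-keto reductases of steroid metabolism, by 5.40 ± 0.36 and 5.29 ± 0.63 (AKR1C2 by 4.29 and 6.29 without miR-195 replicates 1 and 2), SLPI, a secreted protease inhibitor, by 4.89 ± 0.42, and CPQ, a carboxypeptidase, by 4.36 ± 0.22. The AKR1C genes are close paralogs, and how far their probe sets read each other was not tested. Of 33 respiratory chain genes 21 rose and 2 fell, over all genes and over the list alone (median 0.62 relative to all genes; camera, adjusted p = 0.00461, and 0.272 with an estimated correlation), with NDUFS7 at 1.79 ± 0.19 and UQCRC2 at -1.66 ± 0.21. Of 19 genes of NF-kB and inflammation 10 rose and none fell, and of 29 interferon response genes 15 rose and 1 fell, with the same counts over each list alone. Both lists had a camera adjusted p = 0.0460, but 0.631 and 0.677 with an estimated correlation, and medians of 0.34 and 0.35 relative to all genes. The complement protein C3 rose by 3.93 ± 0.52, though by 2.50 without miR-195 replicate 1 and 5.36 without miR-195 replicate 2, the adhesion molecule ICAM1 by 2.93 ± 0.33 (2.15 and 3.71 without the same arrays), the cytokine IL6 by 2.03 ± 0.25 and the chemokine CCL2 by 1.51 ± 0.30. UBE2L6 and PSMB9, which conjugate ISG15 and process antigens, rose by 1.98 ± 0.27 and 1.94 ± 0.29. After quantile scaling within each line both lists had an adjusted p = 0.0505, with an offset of 16 they had 0.0704 and 0.0721, and without the signal filter the interferon list had 0.121. Without miR-195 replicate 1 the adjusted p were 0.316 for NF-kB and 0.109 for interferon, and without Control replicate 2 they were 0.180 and 0.105.

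In this comparison 7513 genes passed, 4644 higher and 2869 lower, and 2199 and 2346 of these changed by at least 1. After each array median was subtracted 5499 were higher and 2756 lower. The poly-A spike-in signal was higher by 1.47 than the 5.54 ± 0.09 (SD, n = 2) of the Control arrays, and that of the probe sets for 18S ribosomal RNA by 1.55, beside each of these groups. Markers of immune and blood cells were higher for 4 of 12 genes and those of fibroblasts and endothelium for 2 of 11, with list medians 0.02 above and 0.04 below that of all genes, and neither list passed camera.

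In DU145 cells miR-30d was accompanied by falls in the same mitotic and replication lists and by rises of several interferon response, histone and respiratory chain genes. Of 33 genes of G2/M and mitosis 18 fell and none rose (20 and 1 adjusted over the list alone; median -0.86; camera, adjusted p = 1.51e-11, and 0.0776 with an estimated correlation). CENPF fell by 3.70 ± 0.31, CENPE by 3.38 ± 0.23, KIF11 by 2.14 ± 0.25 and AURKB, the kinase of the chromosomal passenger complex, by 1.73 ± 0.22. Of 33 genes of G1/S and DNA replication 9 fell and none rose (11 and none adjusted over the list alone; median -0.50; camera, adjusted p = 1.59e-05, and 0.0776 with an estimated correlation), with POLA1 lower by -1.83 ± 0.30 and MCM10 by -1.53 ± 0.27, the latter by -0.75 (adjusted p = 0.144) with the mean of all probe sets. Of 29 interferon response genes 11 rose and none fell (13 and none adjusted over the list alone; median 0.53; camera, adjusted p = 4.53e-06, and 0.279 with an estimated correlation). MX1, a GTPase that restricts viruses, rose by 2.96 ± 0.48, though by 1.61 without miR-30d replicate 1 and 4.31 without miR-30d replicate 2, IFIT1 by 2.12 ± 0.37 and IFIT3 by 2.00 ± 0.26. Of 10 histone genes 6 rose (7 adjusted over the list alone; camera, adjusted p = 7.31e-06, and 0.0776 with an estimated correlation), with H2AC6 at 2.23 ± 0.23 and H1-2 at 1.98 ± 0.24. Of 33 respiratory chain genes 7 rose (9 adjusted over the list alone; camera, adjusted p = 4.53e-06, and 0.0776 with an estimated correlation), with NDUFA2 at 0.93 ± 0.19.

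The largest rises included those of AKR1C3, by 6.16 ± 0.36, and AKR1C2, by 5.80 ± 0.63. Their size depended on single arrays, with AKR1C3 at 5.36 and 6.97 and AKR1C2 at 4.15 and 7.45 without miR-30d replicates 1 and 2, and the Control mean of AKR1C2, 2.58, lay below the array median of 3.72. CD24, a mucin-like surface protein of epithelial cells, rose by 5.61 ± 0.32, SLPI by 4.64 ± 0.42 (3.43 and 5.86 without the same arrays), CDH1, the epithelial adhesion molecule E-cadherin, by 3.88 ± 0.38 and SCNN1A, a subunit of the epithelial sodium channel, by 3.56 ± 0.38. The SDs of CDH1 were 1.03 with miR-30d and 0.69 in Control (n = 2 each). Those of SCNN1A were 0.87 and 0.74, so the pooled standard errors of both genes understate their spread in DU145 cells. UACA, a scaffold protein linked to apoptosis, fell by 4.34 ± 0.33 and DSP, the desmosomal plaque protein desmoplakin, by 3.53 ± 0.29. KRT8 and KRT18, paired keratins of simple epithelia, rose by 1.52 ± 0.25 and 1.37 ± 0.30. Of 23 epithelial markers 4 rose and none fell, over all genes and over the list alone, and the list missed the threshold (camera, adjusted p = 0.149). Its median was -0.04 while its mean was 0.32. Of 27 immediate early and AP-1 genes 7 rose and 1 fell (8 and 1 adjusted over the list alone; camera, adjusted p = 0.0205, and 0.361 with an estimated correlation), with EGR1 at 2.58 ± 0.43 (1.73 without Control replicate 1) and MYC at 1.25 ± 0.24. This list was not past the threshold without miR-30d replicate 2 (adjusted p = 0.0643) or Control replicate 2 (adjusted p = 0.129). Of 19 cholesterol synthesis genes 2 rose, over all genes and over the list alone (camera, adjusted p = 0.0373, and 0.589 with an estimated correlation). The list was not past the threshold without miR-30d replicate 1 (adjusted p = 0.0899), miR-30d replicate 2 (adjusted p = 0.0636) or Control replicate 1 (adjusted p = 0.181). Of its members, MSMO1, a sterol oxidase, rose by 1.32 ± 0.42 and lost the call without any 1 of the 4 arrays (adjusted p up to 0.183), and HSD17B7, a sterol reductase, rose by 1.37 ± 0.39 and kept it in 1 of the 4 cases (adjusted p up to 0.470).

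Of 36 reported miR-30 targets 5 fell and 1 rose (6 and 1 adjusted over the list alone), and the list missed the threshold (camera, adjusted p = 0.0591). TWF1, an actin-binding protein, fell by 1.55 ± 0.25 and CHD1, a chromatin remodeller, by 2.18 ± 0.31. PPP1R12A had a difference of -1.34 ± 0.59 (adjusted p = 0.159), SOCS1 of 0.34 ± 0.21 (adjusted p = 0.369), JUN of -0.38 ± 0.25 (adjusted p = 0.392) and VEGFA of 0.27 ± 0.19 (adjusted p = 0.437). DICER1 fell by 1.88 ± 0.28. In all, 1991 genes passed, 1027 higher and 964 lower, and 590 and 619 of these changed by at least 1. The count was 1106 without miR-30d replicate 1 and 1097 without Control replicate 1. It was 970 after quantile scaling across all arrays, 3036 with an offset added to the signal, and 1093, of which 458 were higher, with the DU145 arrays fitted alone. The poly-A spike-in signal differed from Control by 0.11, and the probe sets for 18S ribosomal RNA by 1.18, with 12.33 and 11.21 in the miR-30d arrays against 10.55 and 10.64 in Control.

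**Figure D4:**
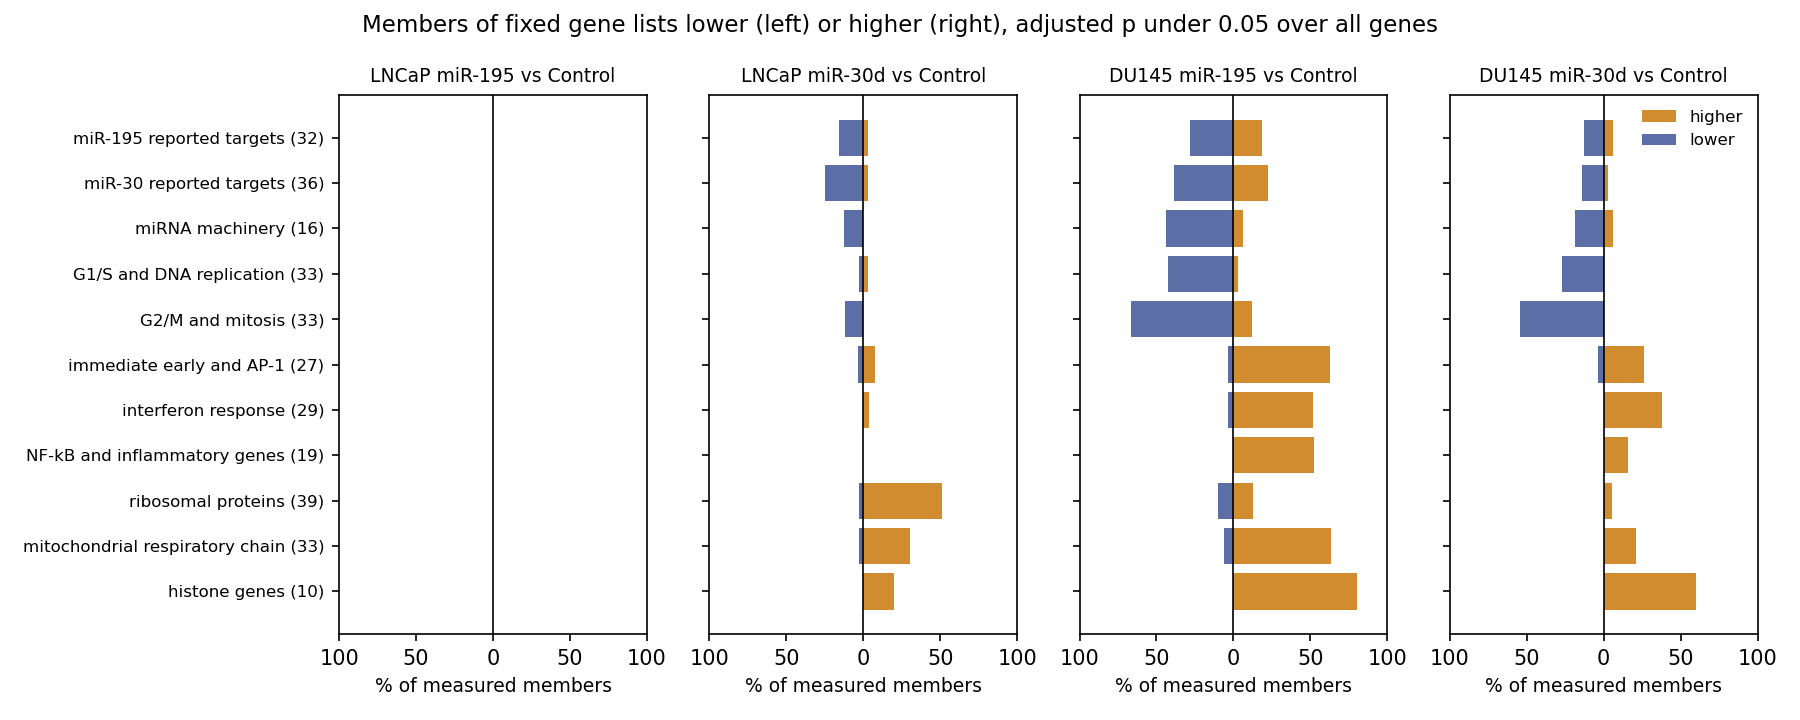
Bars give the percentage of measured members of 11 gene lists (number in brackets) that were higher (right) or lower (left) at an adjusted p under 0.05, in each microRNA comparison against Control. In DU145 cells 22 of 33 G2/M genes are lower with miR-195 and 18 of 33 with miR-30d, and in the arrays labelled LNCaP 20 of 39 ribosomal protein genes are higher with miR-30d.

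In DU145 cells the differences from Control overlapped between the microRNAs, both compared with the same Control arrays. The log2 differences correlated across genes at r = 0.629, against 0.499 for simulated groups without change that share a Control, with a covariance of 0.437 against 0.0356. There were 779 genes lower with both and 747 higher with both, counts that the shared Control arrays raise by an amount not estimated here. In the arrays labelled LNCaP the correlation was 0.519 (0.413 to 0.574 with each array left out), on both sides of the simulated value, with a covariance of 0.0598 against 0.0239. There 19 genes were lower with both, where independent lists would share 1.1, a count that the shared Control arrays raise. The simulated groups hold no change, and changes of a single microRNA lower r. An r near the simulated value therefore cannot tell whether the differences overlapped over all tested genes. Over the 1669 genes with a mean over 7 in those arrays, r was 0.649 against a simulated 0.4997. With each array left out it ran from 0.502 to 0.733, the lowest barely above the simulated value. The covariance over these genes was 0.162 against 0.0186. For these genes r and the covariance lay above the simulated values, for r by a margin that depended on single arrays. The simulation holds only array noise. In either line it therefore cannot tell an overlap of the microRNA effects from a state of the Control line. Across lines, where no array is shared, the differences for miR-195 correlated at r = 0.071 and those for miR-30d at r = 0.147. A closer relation crossed the microRNAs: LNCaP miR-30d and DU145 miR-195 correlated at r = 0.343, and at r = 0.741 over the 1669 genes with a mean over 7 in the arrays labelled LNCaP. Over those 1669 genes miR-195 correlated across lines at r = 0.389 and miR-30d at r = 0.313. There were 454 genes lower in both LNCaP miR-30d and DU145 miR-195, where independent lists would share 128. Their median difference was -1.28 in LNCaP miR-30d, -2.03 in DU145 miR-195, -0.39 in LNCaP miR-195 and -0.50 in DU145 miR-30d, where 104 of the 454 were lower and 6 higher. The choice of genes fixes the sign of the first 2 medians. The other medians use the same Control arrays, so the choice pulls them down too. For these genes LNCaP Control lay above Wildtype by a median of 0.24.

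**Figure D5:**
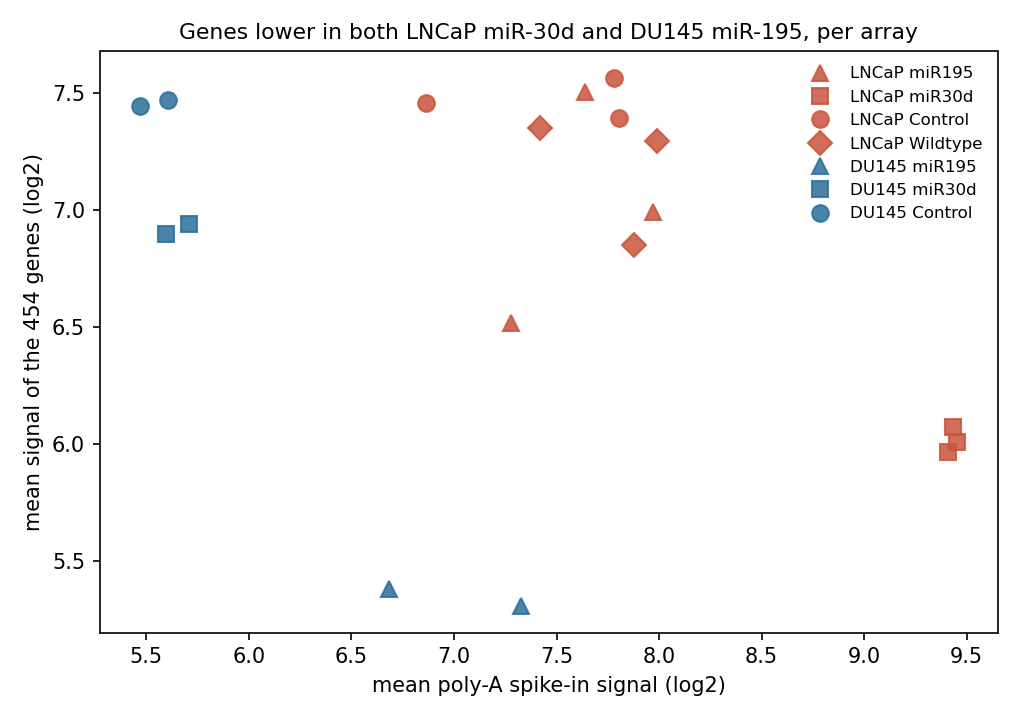
Each point is 1 array, with the mean log2 signal of the poly-A spike-in transcripts on the horizontal axis and the mean log2 signal of the 454 genes lower in both LNCaP miR-30d and DU145 miR-195 on the vertical axis. Color gives the line label and shape the construct; the genes were chosen for being lower in those groups, which average 6.02 and 5.35 against 7.47 and 7.45 in their Controls.

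Compared with each other in the arrays labelled LNCaP, miR-195 and miR-30d differed at 721 genes, 390 higher with miR-195 and 331 lower. The lists of miR-30 targets, miR-195 targets and microRNA machinery passed camera toward higher values with miR-195, at medians of only 0.10, 0.01 and 0.11 (adjusted p of 0.00204, 0.0477 and 0.0464, and of 0.197, 0.238 and 0.197 with an estimated correlation), with 7, 3 and 2 members higher and none, 1 and none lower. Adjusted over the list alone, 8, 7 and 3 were higher and 2, 1 and 1 lower. The ribosomal protein and respiratory chain lists passed as lower, at medians of -0.45 and -0.32, with 14 of 39 and 5 of 33 lower, 1 of each higher, and 20 and 10 lower and 2 and 2 higher adjusted over the list alone. Their adjusted p were 0.324 and 0.197 with an estimated correlation. The miR-195 target list had an adjusted p of 0.121, 0.0775 and 0.0591 without miR-195 replicates 1, 2 and 3, and of 0.151 and 0.0541 without miR-30d replicates 1 and 3. The machinery list had 0.101 without miR-195 replicate 1 or miR-195 replicate 3 and 0.0931 without miR-30d replicate 1. The number of lists past the threshold was 3 without miR-195 replicate 1 or miR-195 replicate 3. The count was 477 without miR-195 replicate 3, 466 without miR-30d replicate 2 and 443 without miR-30d replicate 3. In DU145 cells the microRNAs differed at 7138 genes, 4307 higher with miR-195 and 2831 lower. The G2/M list passed camera as lower with miR-195 (adjusted p = 4.38e-04), with 17 of 33 lower and 6 higher (18 and 6 adjusted over the list alone), and with an estimated correlation the adjusted p = 0.666. Without miR-30d replicate 2 its adjusted p was 0.0558 and no list passed, and without miR-195 replicate 2 the number of lists was 3. AKR1C3 did not pass in this comparison, with a difference of -0.77 (adjusted p = 0.0820).

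A test of the difference between lines in the effect of each microRNA found 6149 genes for miR-195 and 1446 for miR-30d. TFEC fell with miR-195 in the arrays labelled LNCaP and had a difference of 0.10 in DU145 cells. MYBL1 fell by 5.54 in DU145 cells and differed by 0.08 in the arrays labelled LNCaP. For miR-30d, AKR1C3 had a difference of 6.16 in DU145 cells and 0.49 in the arrays labelled LNCaP, and FOXP1, a forkhead transcription factor, of 2.38 and -2.60. Without DU145 Control replicate 1 the miR-30d count was 898, and without DU145 miR-30d replicate 1 it was 945. Between the Controls of both lines 13289 genes differed, 5062 higher under the DU145 label and 8227 lower. Of the 39 ribosomal protein genes 38 were higher under the DU145 label, as were 31 of 33 respiratory chain genes, 29 of 33 G2/M genes, 25 of 33 G1/S genes and 18 of 31 hypoxia and glycolysis genes, and 12 of 12 immune and blood cell markers and 11 of 11 markers of fibroblasts and endothelium were lower. Of the DU145 identity markers 12 of 14 were higher. The adjusted p of these lists with an estimated correlation were 0.0669, 0.0372, 0.0669, 0.0557, 0.179, 0.173, 0.0669 and 0.0557, in that order.

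Of the 25 lists, 12 passed camera in none of the 7 comparisons within a line. These were the lists of androgen-responsive genes, epithelial, mesenchymal and neuroendocrine markers, angiogenesis, the unfolded protein and ATF4 response, p53 targets, apoptosis regulators, LNCaP identity markers, DU145 identity markers, immune and blood cell markers, and fibroblast and endothelial markers. Their lowest adjusted p was 0.149, for the epithelial markers in DU145 miR-30d cells.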

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

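The comparisons between lines and the splits of arrays were planned, and the tests of why AKR1C3 rose and of the falls shared across lines were chosen after results were seen. The effect of the microRNAs differed between lines at 6149 genes for miR-195 and at 1446 for miR-30d. The largest differences for miR-195, DU145 minus LNCaP, were SCARNA14 at 5.89, AKR1C3 at 5.68, AKR1C2 at 5.62, TFEC at 5.54 and SLPI at 5.03, and MYBL1 at -5.62, DNAJC2 at -5.29, SMC2 at -5.15, MAP3K2 at -5.13 and TOP2A at -4.93. For miR-30d they were AKR1C2 at 5.98, CD24 at 5.74, AKR1C3 at 5.67, FOXP1 at 4.98 and SLPI at 4.44, and UACA at -4.18, DNAJC15 at -4.14, CENPF at -3.75, DSP at -3.65 and CENPE at -3.56. Because the arrays labelled LNCaP lack the signal of many common human transcripts, these differences do not show how the 2 lines respond.

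The steroid-metabolizing reductase AKR1C3 rose in both DU145 microRNA lines. A single Control array does not account for it, since without either array the lowest rise was 5.23 and the highest was 6.33, with an adjusted p of at most 1.14e-07. Here the lone remaining Control array is assumed to vary like the other groups. A state of the Control line itself would raise AKR1C3 alike against both microRNAs. The direct difference, miR-195 minus miR-30d, was -0.77 (adjusted p = 0.0820), and as both comparisons share the Control arrays this cannot tell a state of the Control from an effect of both microRNAs. An untransduced DU145 group would separate them.

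The genes lower in both LNCaP miR-30d and DU145 miR-195 pair different microRNAs. If the microRNA named by the label were the whole cause, LNCaP miR-30d would be closest to DU145 miR-30d. Over all tested genes its r with DU145 miR-195 was instead greater by 0.196 (0.170 to 0.223 with each array left out, jackknife standard error 0.0424), and by 0.428 (standard error 0.0656) over the 1669 genes with a mean over 7. This difference follows from the correlations given above. It does not exclude the microRNA, since labels exchanged within a line would give it too and different microRNAs can reach the same genes. If the microRNA labels had been exchanged within a line, LNCaP miR-195 would be closer to DU145 miR-30d than to DU145 miR-195. The difference in r was -0.0326 (-0.0507 to -0.00154, standard error 0.0396) over all tested genes and -0.262 (standard error 0.0594) over the 1669 genes. By a bar of 2 standard errors in both sets of genes, set after the values were seen, this test cannot tell, and both explanations stay open.

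RNA input or amplification could lower the same transcripts in both groups, since the poly-A spike-in signal was higher by 1.95 in LNCaP miR-30d and by 1.47 in DU145 miR-195. The amount of spike-in added per sample was not checked, so this signal need not reflect RNA input. Within groups of the arrays labelled LNCaP the spike-in signal and the mean of these genes had r = 0.140 (n = 12, exact permutation p = 0.758 over 1296 permutations). The rank correlation was 0.077 (p = 0.883), and r was -0.289 without the 2 farthest arrays. With so few arrays this test cannot tell.

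The arrays of each LNCaP comparison can be split into 10 pairs of groups of 3. The split by label gave 27 genes for miR-195 where no other split gave more than 1, 1000 for miR-30d where no other gave more than 0, 7 for Control against Wildtype where no other gave more than 0, and 721 for miR-195 against miR-30d where no other gave more than 1. In each case 1 of the 10 splits, the real one, had as many genes. So few splits cannot give a share under 0.05, and the test cannot tell.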

How the results depend on the processing

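The alternatives that use only DU145 arrays for probe choice and filter, or only genes with a mean over 7 in the arrays labelled LNCaP, were chosen after results were seen. With them DU145 miR-30d had 1251 genes (534 higher, 717 lower), LNCaP miR-195 had 58 (12 higher, 46 lower) and LNCaP miR-30d had 626. FGF2 then rose with miR-195 in DU145 cells by 1.95 (adjusted p = 3.26e-04), and TIGAR had a difference of 0.46 with miR-30d (adjusted p = 0.302), each with the sign opposite to the fit of all arrays.

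With an offset of 64 on the linear scale LNCaP miR-195 had 49 genes, DU145 miR-30d 3036 and the miR-30d difference between lines 2529. Quantile scaling across all arrays gave 42 for LNCaP miR-195, of which 19.0% were higher against 7.41%, 970 for DU145 miR-30d, 11 for Control against Wildtype, of which 72.7% were higher against 85.7%, and 947 for the miR-30d difference between lines. With array medians subtracted 75% were higher in Control against Wildtype. With the mean of all probe sets the counts were 15 for LNCaP miR-195, 4 for Control against Wildtype and 375 for LNCaP miR-195 against miR-30d. Testing every probe set gave 41, 1612, 17030 and 4984 for the microRNA comparisons in the order LNCaP miR-195, LNCaP miR-30d, DU145 miR-195 and DU145 miR-30d. It gave 15 for Control against Wildtype, 16024 for DU145 miR-195 against miR-30d, and 14075 and 3414 for the differences between lines. Without multi-transcript probe sets Control against Wildtype had 12 genes. Without a trend LNCaP miR-195 had 16.

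Fitting each line alone gave 41 for LNCaP miR-195, 13 for Control against Wildtype and 1093 for DU145 miR-30d, of which 41.9% were higher. With Wildtype in place of Control LNCaP miR-195 had 5. With the replicate number as a block the counts were 31, 955, 7406 and 1874 for the microRNA comparisons, 7 for Control against Wildtype, 679 and 6947 for miR-195 against miR-30d, 6011 and 1347 for the differences between lines, and 12976 between Controls. Residuals of arrays with the same number correlated at a median of -0.014 in the arrays labelled LNCaP, so the numbers do not pair arrays.

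With each array left out the counts ran from 8 to 180 for LNCaP miR-195, 653 to 791 for LNCaP miR-30d, 5984 to 6831 for DU145 miR-195, 1097 to 1753 for DU145 miR-30d, 5 to 6 for Control against Wildtype, 443 to 811 and 5108 to 5758 for miR-195 against miR-30d, 5060 to 6237 and 898 to 1466 for the differences between lines, and 12637 to 13074 between Controls. The lists ran from 1 to 2, 3 to 5, 5 to 8, 5 to 7, 1 to 4, 3 to 5 and 0 to 3 in the order of the first 7 comparisons.

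Lists past the threshold were 1, 4, 8, 7, 4, 5 and 1 in that order. After quantile scaling within lines Control against Wildtype had 2 and LNCaP miR-195 against miR-30d 3. With an offset of 16 DU145 miR-195 had 5 and LNCaP miR-195 against miR-30d 3. Without a filter LNCaP miR-195, Control against Wildtype and DU145 miR-195 against miR-30d had 2 each, and with the replicate block Control against Wildtype had 2. With an estimated correlation all 7 had 0. With fry LNCaP miR-195 had 0, DU145 miR-195 18, DU145 miR-30d 11, Control against Wildtype 0 and DU145 miR-195 against miR-30d 15. The correlation of LNCaP miR-30d with DU145 miR-195 over genes with a mean over 7 was 0.706 after quantile scaling within lines, against 0.741.

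Over 11558 checks of named genes 10977 gave the same call, 449 a weaker one, 118 a stronger one and 14 the opposite sign with a call in either fit. A gene past the threshold in neither fit counts as the same call whatever its sign. The first number is therefore no measure of how stable the called genes are. Over 343 checks of lists past the threshold, 255 gave the same call and 88 a weaker one. The sign changed for MAD2L1 in LNCaP miR-30d with offsets (0.0703 and 0.0217). Without multi-transcript probe sets it changed for ZFHX3 (0.13) and GCC2 (0.0267) in LNCaP miR-195, VEGFA in LNCaP miR-30d (0.11), IGF1R (0.13) and RPL14 (0.10) in DU145 miR-195, RPL37 in DU145 miR-30d (-0.36) and GCC2 in Control against Wildtype (-0.11). With Wildtype in place of Control it changed for PSMG4 (-0.0733) and SMARCA1 (0.17) with miR-195 and STMN1 (-0.19) with miR-30d. The cause was not tested. The planned test of seed sites was not run, and the Control arrays, 3 or 2 per line, could not be split. Signal near background compresses differences, which limits all values for weak genes.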

Other observations

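The lists below and the rule for naming genes were fixed beforehand, and that rule took list members by smallest p in these data. The tests of the identity of the arrays were chosen after results were seen. In DU145 miR-195 cells regulators of apoptosis moved in both directions, 11 of 21 higher and 4 lower. Over all genes of that comparison 4644 of 15087 were higher and 2869 lower. XIAP, which inhibits caspases, fell by 2.46 ± 0.25, while BID and BAD, which promote mitochondrial cell death, rose by 1.59 ± 0.16 and 1.71 ± 0.21. BIRC2, an inhibitor of apoptosis, fell by 2.05 ± 0.28 with miR-30d. Among p53 targets 8 of 26 were higher and 5 lower with miR-195, near the shares over all genes. BAX had a difference of 1.75 ± 0.25 and TP53I3, an oxidoreductase, of 2.87 ± 0.33. FAS, a death receptor, had -1.98 ± 0.26 and RRM2B, a ribonucleotide reductase subunit, -1.79 ± 0.23. TP53I3 rose by 2.76 ± 0.33 with miR-30d.

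Genes of the unfolded protein response also moved in both directions in DU145 miR-195 cells, 12 of 32 higher and 5 lower, not far from the shares over all genes. CEBPB, a stress-induced transcription factor, rose by 2.08 ± 0.24, and HSP90B1, a chaperone of the endoplasmic reticulum, fell by 3.65 ± 0.38, SEL1L, part of the degradation pathway there, by 2.64 ± 0.27 and DNAJB9 by 2.24 ± 0.29. Of 31 genes of hypoxia and glycolysis 9 were higher and 5 lower, again near the shares over all genes. NDRG1 had a difference of 2.72 ± 0.31 and P4HA1, a collagen hydroxylase, of -3.10 ± 0.23. Of 26 angiogenesis genes 12 were higher and 1 lower, with VEGFB at 1.78 ± 0.26 and SEMA3F at 1.69 ± 0.22. None of these lists passed camera.

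The arrays labelled LNCaP lack the signal of many, though not all, genes that nearly all human cells use, and 4 explanations were weighed. Among those with high signal under both labels were RPS14, a ribosomal protein, at 13.36 against 13.14 under the DU145 label, and PGK1, a glycolytic enzyme, at 13.21 against 11.05. Scaling of the lines apart would vanish after quantile scaling across all arrays, yet the median ribosomal protein gene was still lower by -3.04. Degraded RNA would raise the 3′ over the 5′ signal of ACTB, yet this was -2.59 (-2.90 to -2.13), against at least 2.74 in the arrays labelled DU145. That reading needs a 3′ probe set that binds these samples as it binds the others, which the 3′ minus middle values below call into question. Degradation is therefore not excluded. A true difference in transcript levels between the lines would move all probe sets of 1 gene alike, where signal is far from background. Over 24 ribosomal protein genes with several bright probe sets in DU145, the range of LNCaP minus DU145 within a gene had a median of 2.18 (2.12 to 2.33 with each array left out). It was 1.82 over 580 genes with a median fall over 1 between the lines, and at most 0.60 for genes that fell within a line. The falls were not matched in size, and signal near background compresses differences, so these ranges cannot tell. ACTB 3′ minus middle was -4.00 ± 0.20 (SD, n = 12) against 0.96 ± 0.19 (SD, n = 6). The 3′ signal was lower under the LNCaP label (7.765 against 12.03) and the middle signal higher (11.77 against 11.07). A difference in level alone would not move these probe sets in opposite directions. For ACTB such a difference is therefore not the whole cause, though one may exist beside it. RNA of another species could bind human probes unevenly along a gene, and GAPDH 3′ minus middle was -2.22 (-2.68 to -1.89) against 1.42, which is consistent with it but does not name a species or exclude another cause.

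The DU145 miR-195 group lay closer to the arrays labelled LNCaP than the other DU145 groups did. Averaged over pairs of single arrays, its r with each of their groups lay between 0.553 and 0.573, and that of the other DU145 groups between 0.418 and 0.433. Reading the raw probe intensities, or genotyping the remaining RNA, would test the identity of these samples.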
